A study of Homo sapiens with 7 samples.

How the data were processed

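RNA of 7 samples of a dual-reporter human embryonic stem cell line was measured by RNA-seq, undifferentiated and after sorting on days 3, 7 and 14 of cardiac differentiation. Per the labels' protocols, cells were sorted 2 times into a preservative solution, RNA was extracted on spin columns, libraries were made with a TruSeq RNA v2 kit, which does not mark strand, and sequenced as single reads on an Illumina HiSeq. The labels do not say whether the CD13 and ROR2 gate for the day 7 and day 14 fractions was applied on day 3 or on the day of collection. The label field for the cell line differs between samples only in a number that counts upward, and all were treated as 1 line.

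The authors deposited 1 table of FPKM values (fragments scaled by transcript length and by the mapped total of the library) with 1 column per library and gene symbols as identifiers. Per the submitters' processing notes, Cufflinks and the genome build hg19 were used; versions, the aligner, the gene annotation, and any treatment of reads that map to several places are not given in the sources used here. The table holds 23368 genes, of which 106 have blank cells in all libraries and were left out, and 3537 of the remaining 23262 are at 0 in all 7. No coordinates are given, because the reference used for gene names is of another build.

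FPKM divides by transcript length and by a library total. It raises very short genes, and a few small RNA genes took a large part of some columns. MIR612 was 26.6% of the FPKM sum in hESC and 51.6% in day 7 NKX2-5-, and MIR593 20.4% in day 14 aMHC-. A value of 0 can be a failed estimate, since HNRNPC, HNRNPD and ARPC2 were at 0 in 1 or 2 libraries and abundant in others. Of 1414 genes of at least 15 FPKM in the median library (small RNA and histone genes left out), 11 were listed at 0 in at least 1 library. These include heart muscle genes such as MYL7 and NPPB, where a 0 may also be a true absence. No fold is therefore given against a library listed at 0. Reads shared by close paralogs (MYH6 and MYH7, the actin genes ACTA1, ACTA2 and ACTC1, LEFTY1 and LEFTY2, GYPB and GYPE, the metallothionein genes, HSPA1A and HSPA1B) could have been split either way, and values of these genes are uncertain to that extent. The same holds for genes that overlap on opposite strands.

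Absolute depth could not be recovered. Where a gene has 1 or a few reads, its FPKM is a whole multiple of the value of 1 read, so the most frequent ratio of low values between libraries gives their relative depth. That ratio was sharp for 4 of the 6 sorted libraries (the mode held 8.88 to 13.1 times as many genes as the ratios beside it), less so for day 14 aMHC- (3.85 times), and not usable for day 7 NKX2-5- (1.77 times). Values near 1 FPKM or lower rest on few reads, most of all in day 7 NKX2-5+.

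Groups were taken from the sample labels, with 1 library each. No spread between replicates exists, so no statistical test, p-value or standard deviation of a group is given. In all, 7 comparisons were made, each as log2 of (FPKM + 1) in one library over (FPKM + 1) in the other. A gene was called higher or lower when this ratio was at least 2 in size (4-fold) with at least 5 FPKM in the higher library. Ratios on this scale understate differences of low genes, and folds printed in the text are plain quotients of FPKM. A gene list was called higher or lower when the median of its members was at least 1 in size. The percentile of that median among 10000 random lists of the same size, matched on mean expression in 20 bins, describes these libraries and is no test.

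The gene lists, the comparisons, the size rules and the choice of named genes were fixed before the data were examined. The 25 lists cover pluripotency, primitive streak, cardiac mesoderm, presomitic mesoderm, definitive endoderm, hepatic and visceral endoderm, neuroectoderm, cardiac transcription factors, sarcomere, calcium handling and ion channels, natriuretic peptides, muscle energy metabolism, endothelium, blood, smooth muscle, fibroblast and matrix, epicardium, WNT targets, NODAL pathway, BMP targets, epithelial junctions, mesenchymal transition, proliferation, immediate early genes and housekeeping, beside the sort genes. All 348 list genes were in the table. Some genes stand on more than 1 list. Genes were named by a rule in 3 parts, which takes the sort genes, up to 4 passing members of each list in each comparison (or the 2 with the largest ratios as values where fewer than 2 pass), and the 8 genes with the highest and the 8 with the lowest ratios outside small RNA, histone and unnamed genes. Of the genes this rule takes, the text names many, while some are not reported here, and it gives further values of genes so named in other libraries.

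Alternatives were a pseudocount of 0.1 or 5, no minimum FPKM, scaling each library to a sum of 1000000, median-ratio scaling over 7780 genes above 1 FPKM in all libraries, and leaving out 1692 small RNA and histone symbols with the sum kept equal. Leaving out genes listed at 0 in either library, and leaving out the day 7 NKX2-5+ library, were added after seeing the data. The calling step was tested on counts drawn from the real FPKM values at an assumed 10 reads per FPKM unit, since absolute depth is unknown, with simulated gene noise in 1 library (23262 genes, 50 genes at each fold). For the day 7 pair it recovered 10% of genes planted at 3-fold, 82% at 6-fold, 98% at 12-fold and 100% at 24-fold. Planted genes had at least 10 FPKM in the library drawn from, outside small RNA and histone genes, and both simulated libraries had the same depth. The simulation therefore covers the calling step alone, without lower genes or unequal depth. It does not cover the spread between samples, which these libraries cannot give. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used.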

Results

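The libraries follow human embryonic stem cells (hESC) through differentiation toward heart muscle. The line carries an eGFP reporter at NKX2-5, a transcription factor gene of early heart cells, and an mCherry reporter of alpha-MHC, the cardiac myosin heavy chain encoded by MYH6. Cells were separated by flow cytometry. On day 3 the sort used the surface proteins CD13 (encoded by ANPEP) and ROR2, on day 7 the NKX2-5 reporter, and on day 14 both reporters. The series describes the day 7 and day 14 fractions as descended from, or gated within, the CD13+/ROR2+ population. RNA of undifferentiated hESC and of the 6 sorted fractions was sequenced, with 1 library per group, so that no difference between groups has a replicate check. Expression is given in FPKM for 23262 genes.

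Depth is known only in relative terms. From the steps between low values, the day 7 NKX2-5+ library had 0.595 times the depth of the hESC library, day 3 CD13+/ROR2+ 2.68 times, day 3 CD13-/ROR2- 1.33 times, day 14 aMHC+ 2.0 times and day 14 aMHC- 3.03 times, the last with a less sharp estimate. Day 7 NKX2-5- could not be placed this way. Genes of at least 1 FPKM numbered 9699 in day 7 NKX2-5+ and between 10656 and 10830 in the other 6 libraries. Across 13506 genes, which are not independent replicates, the day 14 pair was most alike (Pearson r = 0.950, log2 scale), followed by hESC and day 3 CD13-/ROR2- (r = 0.890). The day 3 pair gave r = 0.843 and the day 7 pair r = 0.837.

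The genes behind the sorts were read in all libraries. ANPEP stood at 12.0 FPKM in day 3 CD13+/ROR2+ against 0.984 in CD13-/ROR2- and 0.330 in hESC. ROR2 stood at 20.6 against 3.16 and 1.12 FPKM. In the later fractions ANPEP was lower, at 0.145 FPKM in day 7 NKX2-5+ and 1.72 in NKX2-5-. It was at 0.0152 in day 14 aMHC+ and 0.0731 in aMHC-. Of the 4 sort genes, 2 were at least 4-fold lower in day 7 NKX2-5+ than in day 3 CD13+/ROR2+ (1 after median-ratio scaling). These are RNA levels, not surface protein, and do not tell on which day the CD13 and ROR2 gate was applied. NKX2-5 was 70.2 FPKM in day 7 NKX2-5+ and 1.18 in NKX2-5-, and 63.2 and 85.5 in the day 14 aMHC+ and aMHC- fractions, both of which were sorted as NKX2-5+. MYH6 was 531 FPKM in day 7 NKX2-5+, 43.4 in NKX2-5-, 342 in day 14 aMHC+ and 136 in aMHC-, where the 2.52-fold difference of the day 14 pair falls short of the size rule.

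**Figure D1:**
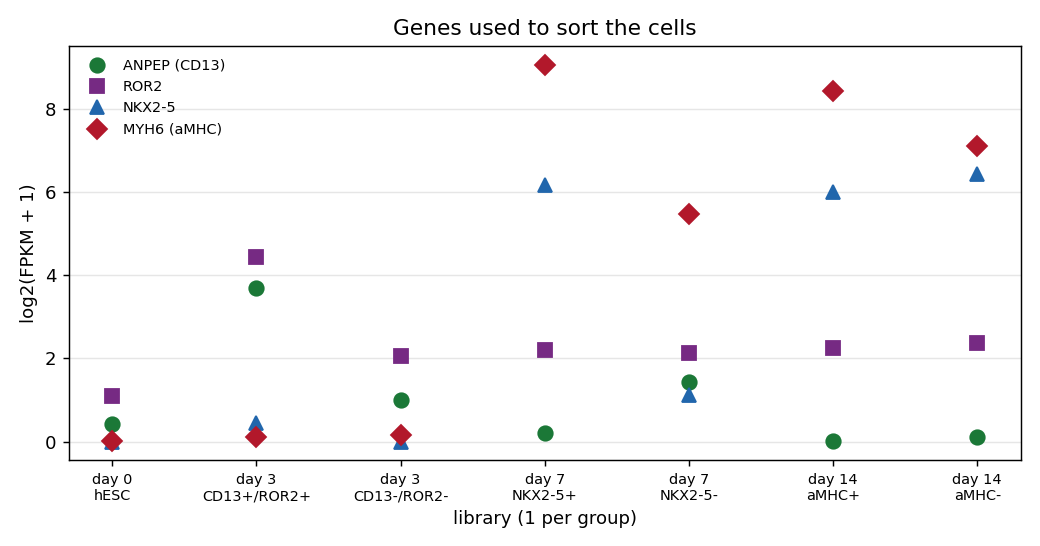
Each point is log2(FPKM + 1) of 1 sort gene (vertical axis) in 1 library (horizontal axis, 1 library per group, no error bars). ANPEP and ROR2 peak in day 3 CD13+/ROR2+ (12.0 and 20.6 FPKM), and NKX2-5 is at 70.2, 63.2 and 85.5 FPKM in the 3 fractions sorted as NKX2-5+.

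The first comparison asks what CD13 and ROR2 separate on day 3. The CD13+/ROR2+ library, labelled mesoderm progenitor, had higher levels of many cardiac mesoderm genes and lower levels of many pluripotency genes than the CD13-/ROR2- library, labelled endoderm progenitor. APLNR, the apelin receptor of migrating mesoderm, was 321 against 8.79 FPKM (36.5-fold), the heart transcription factor gene GATA4 47.4 against 1.48 (32.1-fold) and HAND1 118 against 8.29 (14.2-fold). SOX2 and NANOG, which maintain pluripotency, stood at 0.295 and 0.660 FPKM in CD13+/ROR2+ against 68.0 and 27.5 in CD13-/ROR2-. Outside small RNA and histone genes, the gene with the highest log2 ratio was CER1, a secreted NODAL, BMP and WNT antagonist, at 1736 against 11.7 FPKM (148-fold).

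Of the 20 cardiac mesoderm genes, 10 were at least 4-fold higher and 0 lower, with a list median of 2.0 on the log2 scale, at percentile 100 of random lists of matched expression. SNAI2 (25.0 against 0.529 FPKM) and DKK1 (33.8 against 0.920) were among them. The definitive endoderm list was also higher in CD13+/ROR2+ (median 2.16, 7 of 15 members higher and 2 lower). Its higher members included GATA6, which the mesoderm list shares (79.4 against 5.34 FPKM), CXCR4 (10.2 against 0.507) and SOX17 (17.8 against 2.71), while the epithelial cadherin gene CDH1, also on that list, was lower (3.15 against 45.0). The pluripotency list was lower (median -2.0, 8 of 17 members lower and 0 higher), with TERF1 at 8.40 against 83 FPKM and DPPA4 at 39.9 against 272.

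Junction genes and mesenchymal genes lay on opposite sides. The epithelial list had a median of -1.87 (5 of 12 lower, 0 higher). GRHL2, a transcription factor of epithelia, was at 0.489 against 7.51 FPKM, the splicing regulator ESRP1 at 7.02 against 41.9 and CLDN7 at 1.92 against 14.5. The mesenchymal transition list had a median of 1.80 (4 of 12 higher, 0 lower), with vimentin (VIM) at 272 against 27.6 FPKM, N-cadherin (CDH2) at 63.9 against 6.28 and CDH11 at 18.6 against 0.730. The primitive streak list moved less as a whole (median 0.52, 4 of 15 higher, 1 lower). LHX1 (73.7 against 0.245 FPKM), FGF17 (37.0 against 0.328) and GSC (20.2 against 0.963) were higher and WNT8A lower (1.68 against 14.6).

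Of the BMP targets, ID1 (17.4 against 192 FPKM) and ID2 (8.44 against 44.3) were lower in CD13+/ROR2+, and the list median of -0.95 was just short of the size of 1 that counts as lower, which it passed after median-ratio scaling (-1.02). WNT targets had a median of 0.19, with LGR5 at 49.8 against 0.517 FPKM. NODAL pathway genes had a median of 0.52. Cardiac transcription factors had 6 of 23 members higher and a median of 0.31, with IRX3 at 12.5 against 0.639 FPKM. Medians of the sarcomere, hepatic, neuroectoderm, presomitic mesoderm, blood, endothelial, epicardial, smooth muscle and fibroblast lists lay between -0.16 and 0.11. On the hepatic list 1 of 15 genes passed the size rule, APOA2 at 27.0 against 1.48 FPKM. Among the remaining genes with the highest and lowest ratios were CYP26A1, a retinoic acid hydroxylase (86.4 against 0.947 FPKM), GRP (68.1 against 0.872), PLA2G2A (0.359 against 31.6), PDGFA (0.267 against 19.4) and TFAP2A (0.0931 against 16.2).

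In all, 217 genes were at least 4-fold higher and 149 lower in CD13+/ROR2+, among 5875 genes of at least 5 FPKM in either library. With a pseudocount of 5 these were 100 and 43, with list medians of 0.95 for definitive endoderm, -0.74 for epithelial and 0.79 for mesenchymal genes, all short of the size of 1. With every library scaled to the same sum of FPKM they were 487 and 512. That setting raises all values against the fixed pseudocount and minimum, so it also loosens the size rule. HNRNPD and ARPC2, listed at 0 in CD13-/ROR2-, enter these counts although most cells use them, and such zeros can be failed estimates.

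Against hESC, the CD13+/ROR2+ library had lower levels of many pluripotency genes and higher levels of many mesoderm genes, and the CD13-/ROR2- library had higher levels of fewer mesoderm genes. MIXL1, a transcription factor gene of the primitive streak, was at 210 FPKM in CD13+/ROR2+ and 82.0 in CD13-/ROR2- against 1.43 in hESC. EOMES was at 71.0 and 14.9 FPKM and listed at 0 in hESC. POU5F1 was at 154 FPKM in hESC, 64.8 in CD13-/ROR2- and 11.2 in CD13+/ROR2+. NANOG was at 36.5, 27.5 and 0.660 FPKM in the same order, whereas SOX2 was at 26.3, 68.0 and 0.295.

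In CD13+/ROR2+ over hESC, 15 of 20 cardiac mesoderm genes were at least 4-fold higher (median 3.75), 8 of 15 primitive streak genes (median 2.46) and 8 of 15 definitive endoderm genes (median 2.38, 2 members lower). APLNR was at 321 against 0.25 FPKM, HAS2 at 114 against 0.922 and GATA4 at 47.4 against 0.121. HAND1 (118 FPKM), GATA6 (79.4) and SOX17 (17.8) were listed at 0 in hESC. The mesenchymal list had a median of 2.03 (5 of 12 higher) and the epithelial list -1.87 (5 of 12 lower), with CLDN4 at 0.0875 against 6.50 FPKM and EPCAM at 11.3 against 57.1. The pluripotency list had a median of -2.25 with 8 of 17 lower. WNT targets (median 1.69), BMP targets (median 1.37, with BMP4 at 77.1 against 1.17 FPKM) and immediate early genes (median 1.01, or 0.95 after median-ratio scaling) were higher. MFAP4, a matrix protein gene, reached 486 FPKM against 2.85, and THY1 was at 2.94 against 83.6.

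In CD13-/ROR2- over hESC, no pluripotency gene passed the size rule in either direction (0 of 17, median -0.33). The primitive streak list was higher (median 1.39, 5 of 15), with the gene T, which encodes brachyury, at 18.7 against 0.0485 FPKM and WNT8A at 14.6 against 0.0669. T stood at 7.32 FPKM in CD13+/ROR2+. Cardiac mesoderm genes were higher too (median 1.22, 6 of 20), with MSX2 at 19.4 against 0.158 FPKM and BMP4 at 19.0 against 1.17. BMP targets had the highest median of the lists in this comparison (2.28, 6 of 10 higher), with ID1 at 192 against 20.7 FPKM and ID2 at 44.3 against 3.07. Definitive endoderm genes had a median of 0.29, but 1.05 and past the size of 1 at equal sums of FPKM. Of these, 2 of 15 were higher, CER1 (11.7 against 0.549 FPKM) and GATA6 (5.34, listed at 0 in hESC). Immediate early genes were higher (median 1.79, 4 of 13), EGR1 at 75.4 against 2.16 FPKM and FOS at 32.2 against 1.79. DUSP6, a target of FGF and ERK signalling, was at 0.772 against 39.5 FPKM and LEFTY1 at 1.34 against 39.1.

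The CD13+/ROR2+ library differed from hESC at 264 genes higher and 149 lower, and the CD13-/ROR2- library at 83 higher and 67 lower. A pseudocount of 5 gave 114 and 46, and 33 and 31, and took the primitive streak and immediate early medians in both comparisons, the WNT, BMP and epithelial medians of CD13+/ROR2+ and the cardiac mesoderm median of CD13-/ROR2- below the size of 1, while an equal sum of FPKM gave 792 and 328, and 437 and 112; without genes listed at 0 in either library the 67 became 40.

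**Figure D2:**
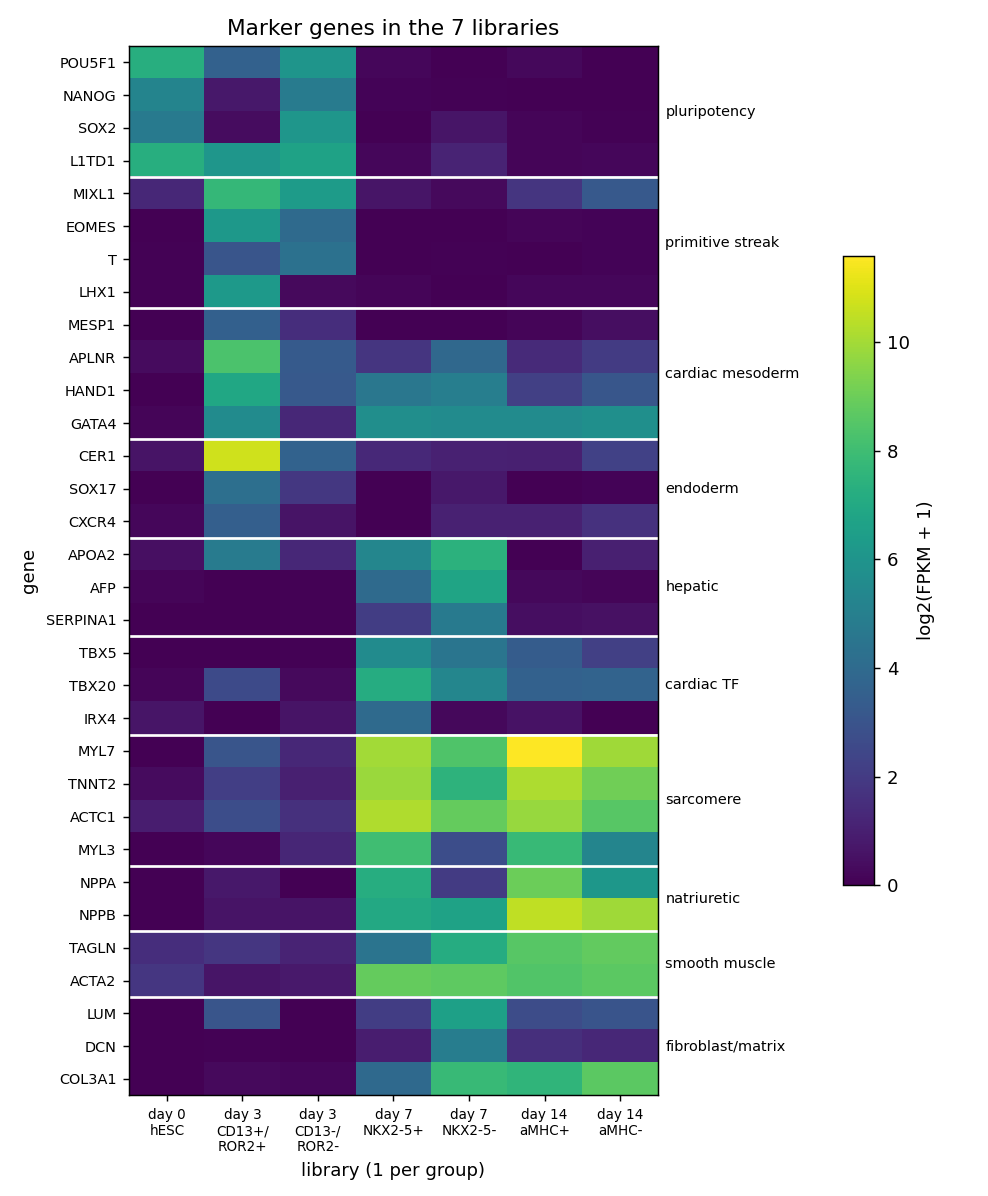
Colour gives log2(FPKM + 1) of marker genes (rows, grouped by fixed gene list at right) in the 7 libraries (columns, 1 per group). Pluripotency genes are high in hESC and in day 3 CD13-/ROR2- (POU5F1 at 154 and 64.8 FPKM), many cardiac mesoderm genes in day 3 CD13+/ROR2+ (APLNR at 321), and sarcomere genes from day 7 on (TNNT2 at 934 in NKX2-5+ and 180 in NKX2-5-).

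The day 7 comparison asks how the fractions with and without NKX2-5 differ. The NKX2-5+ library held the higher levels of many heart muscle transcripts, though not of all. The myosin light chain gene MYL3 was at 262 against 5.73 FPKM, the atrial natriuretic peptide gene NPPA at 146 against 3.07, and muscle creatine kinase (CKM) at 75.7 against 1.25. The NKX2-5- library held the higher levels of many matrix and plasma protein transcripts. Lumican (LUM) was at 93.7 against 3.32 FPKM, COL3A1 at 224 against 14.4 and alpha-fetoprotein (AFP) at 109 against 14.9. Sarcomere transcripts were nevertheless abundant in NKX2-5-, where MYL7 stood at 339 FPKM and ACTC1 at 464, against 1011 and 1189 in NKX2-5+.

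Every comparison with the day 7 NKX2-5+ library carries a general offset. Its median-ratio scaling shift was -0.43 on the log2 scale against NKX2-5-, so list medians here are given after that scaling, followed by the unscaled median in parentheses. Counts of list members are unscaled, with the scaled count added where it differs by over 1.5 times, here and in the later comparisons. The 13 housekeeping genes had a median of -0.31 (-0.67, but 1.18 at equal sums of FPKM). They did not move together, with beta-actin (ACTB) at 393 against 2578 FPKM but GAPDH at 1470 against 1144. A single scaling factor therefore does not level them all. Immediate early genes had a median of -0.73 (-1.07, past the size of 1 only without scaling, and 0.28 at equal sums of FPKM), with JUN at 1.37 against 9.59 FPKM and ATF3 at 0.517 against 5.79.

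Of 25 sarcomere genes, 15 were at least 4-fold higher in NKX2-5+ and 0 lower, with a median of 2.51 (2.08, percentile 100). LDB3 was at 95.2 against 3.83 FPKM and SMPX at 58.7 against 4.98. Energy metabolism genes of muscle had a median of 1.82 (1.41, 6 of 15 higher), with myoglobin (MB) at 24.8 against 0.657 FPKM and COX6A2 at 27.1 and listed at 0 in NKX2-5-. Calcium handling and channel genes had a median of 1.34 (1.02, 5 of 23 higher or 8 after scaling, 1 lower). The ryanodine receptor gene RYR2 was at 28.3 against 2.22 FPKM and KCNIP2 at 20.7 against 0.854, while sarcolipin (SLN) was lower at 2.39 against 24.8. Cardiac transcription factors had a median of 0.74 (0.34, but 2.25 and past the size of 1 at equal sums). Of 23, 5 were higher, among them IRX4 (15.2 against 0.187 FPKM) and SMYD1 (79.6 against 6.57), and 2 lower (1 after scaling), among them TBX18, a factor of the epicardium and sinus node (0.754 against 18.6).

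Of 14 fibroblast and matrix genes, 11 were at least 4-fold lower in NKX2-5+ and 0 higher, with a median of -2.80 (-2.94, percentile 0). Decorin (DCN) was at 0.902 against 28.8 FPKM and PDGFRB at 0.747 against 24.3. The mesenchymal list had a median of -1.89 (-2.14, 6 of 12 lower, and -0.76 at equal sums), with MMP2 at 4.03 against 73.4 FPKM, SPARC at 32.4 against 329 and FN1 at 60.2 against 408. Hepatic and visceral endoderm genes had a median of -1.73 (-2.06, 8 of 15 lower but 4 after scaling, and -0.53 at equal sums), with APOA1 at 3.91 against 29.1 FPKM, APOC3 at 4.57 against 32.9 and SERPINA1 at 3.25 against 25.3. Epicardial genes had a median of -0.90 (-1.03, past the size of 1 without median-ratio scaling but not after it). BNC1 was at 0.483 against 6.69 FPKM and TCF21 at 0.377 against 5.43. Endothelial genes had a median of -0.87 (-0.96, but -2.28 with a pseudocount of 0.1), with PLVAP at 1.89 against 15.6 FPKM and FLT1 at 1.20 against 10.1. The epithelial list had a median of -0.44 (-0.41 unscaled, but -1.60 with a pseudocount of 0.1, 2 of 12 lower). The smooth muscle list had -0.28 (-0.50 unscaled, 3 of 11 lower, and 1.22 at equal sums). At the main pseudocount neither passed with or without median-ratio scaling. Even so, KRT8 (20.7 against 261 FPKM), KRT18 (38.8 against 435), CALD1 (7.41 against 73.7) and TAGLN (21.1 against 144) were lower. ACTA2 was at 456 against 421. The genes with the lowest ratios outside these lists were S100A10 (16.9 against 685), the growth factor gene IGF2 (26.1 against 634), ANXA1 (1.69 against 61.3) and LGALS1 (4.87 against 103).

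The day 7 counts were 101 genes higher and 270 lower in NKX2-5+ (27.2% higher). The split depended on scaling, with 166 and 208 after median-ratio scaling (44.4%), 171 and 179 without small RNA and histone genes and the rest rescaled to equal sums (48.9%) and 2081 and 129 at equal sums of all genes (94.2%), where MIR612 alone is 51.6% of the NKX2-5- sum; a pseudocount of 5 gave 40 and 85, with medians short of 1 for calcium handling (0.43), energy metabolism (0.91), epicardial (-0.52) and immediate early genes (-0.66).

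The step from day 3 CD13+/ROR2+ to day 7 NKX2-5+ compares the sorted mesoderm with the cardiac progenitors named in the labels. Most heart muscle transcripts were low on day 3 and abundant on day 7. Alpha-MHC (MYH6) stood at 531 against 0.0774 FPKM, cardiac troponin T (TNNT2) at 934 against 3.48, cardiac actin (ACTC1) at 1189 against 5.67 and smooth muscle actin (ACTA2) at 456 against 0.567. Many mesoderm genes of day 3 were lower on day 7 (12 of 20 on the cardiac mesoderm list), while GATA4 was at 51.2 against 47.4 FPKM. CER1 was at 1.56 against 1736 FPKM, MIXL1 at 0.573 against 210 and APLNR at 2.44 against 321. EOMES, MESP1, CYP26A1 and SOX17 were listed at 0 on day 7 and stood at 71.0, 10.7, 86.4 and 17.8 FPKM on day 3.

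The scaling shift was -0.69 here, and medians are again given after scaling with the unscaled ones in parentheses. Sarcomere genes had a median of 5.80 (5.13, 22 of 25 higher), natriuretic peptides 6.94 (6.36, 2 of 3), muscle energy metabolism 2.71 (2.17, 8 of 15), calcium handling 2.43 (1.98, 9 of 23) and cardiac transcription factors 2.26 (1.82, 10 of 23 higher and 2 lower, or 1 lower after scaling). TBX5 was at 46.7 against 0.00896 FPKM, TBX20 at 141 against 5.17, the exchanger gene SLC8A1 at 73.9 against 0.515, phospholamban (PLN) at 58.7 against 0.535 and the pacemaker channel gene HCN4 at 39.4 against 1.03. Hepatic genes had a median of 1.93 (1.55, 3 of 15 higher), with AFP at 14.9 against 0.0255 FPKM and RBP4 at 7.67 against 0.411.

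The cardiac mesoderm list had a median of -2.24 (-2.83, 12 of 20 lower), primitive streak -2.07 (-2.42, 8 of 15), definitive endoderm -2.35 (-2.71, 8 of 15), NODAL pathway genes -2.07 (-2.42, 6 of 9) and pluripotency -1.45 (-1.59, 8 of 17). TDGF1, a NODAL co-receptor gene, was at 1.25 against 171 FPKM and L1TD1 at 0.169 against 67.5. Further lists passed the size of 1 without median-ratio scaling but not after it. They were WNT targets at -0.92 (-1.32), proliferation genes at -0.79 (-1.38) and the mesenchymal list at -0.47 (-1.04). MKI67 was at 4.34 against 28.2 FPKM and LGR5 at 0.133 against 49.8. The ribosomal protein gene RPLP0 was at 50.9 against 227 FPKM.

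From day 3 CD13+/ROR2+ to day 7 NKX2-5+, 247 genes were higher and 512 lower. Median-ratio scaling turned the split to 404 and 282, leaving out small RNA and histone genes with the rest rescaled to equal sums to 437 and 274, and equal sums of all genes to 1049 and 787; a pseudocount of 5 gave 103 and 190, and left the pluripotency, hepatic, cardiac transcription factor, calcium handling, WNT and mesenchymal medians below a size of 1.

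The day 14 comparison asks how the aMHC+ fraction, labelled cardiomyocytes, differs from the NKX2-5+ cells without the second reporter. Most genes on the fixed lists stayed within the size rule, and the named genes past it were mainly those of muscle. NPPA was at 514 against 68.5 FPKM (7.5-fold), MYL3 at 222 against 38.3 (5.80-fold), the beta myosin heavy chain gene MYH7 at 50.5 against 10.2 (4.94-fold) and cardiac troponin I (TNNI3) at 32.7 against 7.01 (4.66-fold). CRYAB, a small heat shock protein of muscle, was at 95 against 8.48 FPKM.

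The sarcomere list had a median of 1.40 after scaling (1.23 unscaled, 3 of 25 at least 4-fold higher, 0 lower), and was the 1 list past the size of 1, joined at equal sums by calcium handling (1.14) and natriuretic peptides (1.07). MYL7 was at 3082 against 980 FPKM and TNNT2 at 1133 against 535. COX6A2 (40.2 against 5.50 FPKM), CKM (29.9 against 4.70) and the calcium release gene TRDN (13.0 against 2.01) also passed the size rule. The calcium handling list had a median of 0.48 (0.42) and muscle energy metabolism 0.21 (0.03). Cardiac transcription factors had a median of 0.05 (-0.09) with 0 of 23 passing, where TBX5 was at 9.27 against 3.62 FPKM and HAND1 at 3.56 against 7.58. Fibroblast and matrix genes had a median of -0.52 (-0.71) with 0 of 14 passing, and COL3A1 stood at 188 against 409 FPKM, FN1 at 338 against 716 and POSTN at 16.9 against 38.3. The medians of smooth muscle (0.00, -0.20 unscaled) and proliferation genes (-0.17, -0.34 unscaled) were small.

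The scaling shift of this pair was -0.21. In all, 37 genes were higher and 20 lower (64.9% higher), of which 26 and 20 were small RNA or histone genes. Without these and with the remaining genes rescaled to equal sums the counts were 14 and 0 (100%), without genes listed at 0 in either library 16 and 1, and at equal sums 130 and 23 (85.0%).

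**Figure D3:**
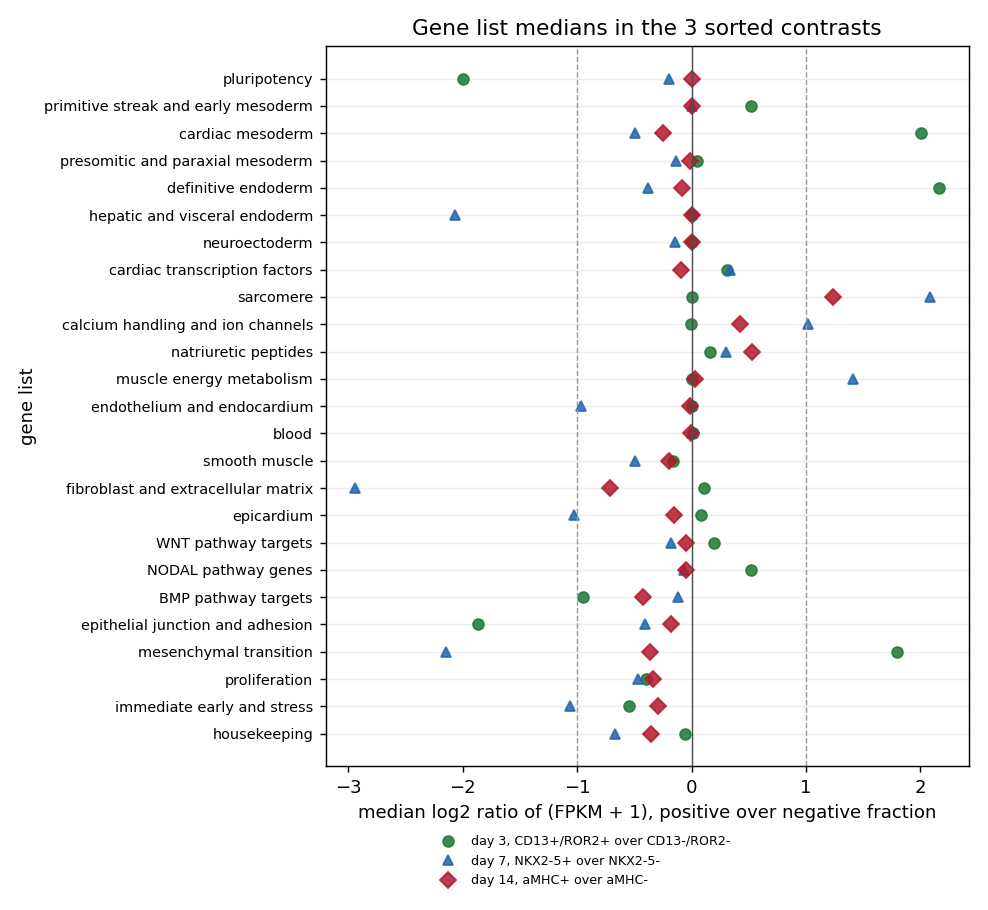
Points are unscaled medians over each list's members of the log2 ratio of (FPKM + 1), positive over negative fraction, for the 3 sorted contrasts (1 library per fraction, no error bars); dashed lines mark a size of 1. Definitive endoderm (2.16), cardiac mesoderm (2.0) and pluripotency (-2.0) lie farthest from 0 on day 3, fibroblast (-2.94), mesenchymal (-2.14), sarcomere (2.08) and hepatic genes (-2.06) on day 7, and on day 14 the sarcomere list (1.23) alone passes the line.

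The step from day 7 NKX2-5+ to day 14 aMHC+ compares the progenitors with the cardiomyocytes named in the labels. The smooth muscle list was higher on day 14 (6 of 11 genes), as were single matrix, keratin and natriuretic peptide genes, while 4 of 15 hepatic genes and 5 of 23 cardiac transcription factor genes were lower. TAGLN was at 383 against 21.1 FPKM, skeletal alpha-actin (ACTA1) at 570 against 5.49, brain natriuretic peptide (NPPB) at 1413 against 125 and KRT8 at 389 against 20.7. Some of these genes were low on day 7 only in NKX2-5+. KRT8 already stood at 261 FPKM in day 7 NKX2-5-, whereas ACTA1 was at 4.06 there. TBX20 was at 11.1 against 141 FPKM, IRX4 at 0.478 against 15.2 and AFP at 0.199 against 14.9. Most sarcomere genes had already been abundant on day 7, with TNNT2 at 1133 against 934 FPKM and MYH6 at 342 against 531.

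The scaling shift was 0.61. After scaling, smooth muscle genes had a median of 1.64 (2.23 unscaled, 6 of 11 higher), with MYH11 at 12.2 against 0.678 FPKM and MYLK at 12.9 against 0.663, and natriuretic peptides 1.35 (1.80, 1 of 3 higher). Immediate early genes had 1.18 (1.56, 4 of 13 or 2 after scaling, and 0.89 without small RNA and histone genes and the rest rescaled), with FOS at 15.6 against 0.564 FPKM and JUNB at 9.83 against 1.06. Lists past the size of 1 only without scaling were fibroblast and matrix genes (0.69, 1.06 unscaled), BMP targets (0.59, 1.03 unscaled) and housekeeping genes (0.49, 1.09 unscaled). Of 14 fibroblast and matrix genes 4 were higher (2 after scaling), and of 13 housekeeping genes 3 (0 after scaling). POSTN was at 16.9 against 0.319 FPKM, ID1 at 247 against 7.40 and ACTB at 2036 against 393. ACTB stood at 2578 FPKM in day 7 NKX2-5-, so its low level was particular to NKX2-5+ on that day. Hepatic genes had a median of -2.08 (-1.66, 4 of 15 lower), and APOA2 was listed at 0 on day 14 against 38.7 FPKM on day 7. Proliferation genes had a median of -1.48 (-0.99, 1 of 20 lower or 7 after scaling), with TOP2A at 1.57 against 9.76 FPKM. Calcium handling genes had -1.14 (-0.58, 1 of 23 lower or 2 after scaling), with KCNIP2 at 3.43 against 20.7. At the main pseudocount both lists passed the size of 1 only after scaling. The sarcomere list had a median of -0.69 (-0.09) with 0 of 25 passing (1 lower after scaling), but -1.03 without small RNA and histone genes and the rest rescaled. Cardiac transcription factors had -0.88 (-0.52), but -1.10 in that setting and -1.63 at equal sums, with 5 of 23 lower, TBX20 and IRX4 among them, and 1 higher, ISL1 (17.4 against 1.69).

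From day 7 to day 14, 408 genes were higher and 44 lower (90.3% higher), but 209 and 111 after median-ratio scaling (65.3%), 119 and 152 without small RNA and histone genes and the rest rescaled to equal sums (43.9%), and 483 and 592 at equal sums of all genes (44.9%); a pseudocount of 5 gave 162 and 15 and left the hepatic, fibroblast, BMP, immediate early and housekeeping medians below a size of 1. Set directly against day 3 CD13+/ROR2+, which leaves out the shallow day 7 library and was chosen after the data were seen, day 14 aMHC+ had 449 genes higher and 348 lower, with a sarcomere median of 5.46 (22 of 25 higher). Against day 7 NKX2-5-, also chosen after the data were seen, it had 184 higher and 135 lower. The sarcomere median was then 2.41 (14 of 25 higher).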

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

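The comparison of the 3 sorted contrasts was planned, and no test was chosen after it. The mesenchymal transition list drew attention because it lay on opposite sides at 2 times. Its median was 1.80 for CD13+/ROR2+ over CD13-/ROR2- on day 3 and -2.14 for NKX2-5+ over NKX2-5- on day 7 (1.71 and -1.89 after median-ratio scaling), a difference that was not tested, with 1 library per fraction. It did not pass the size of 1 on both days with a pseudocount of 5 (0.79 and -1.37) or at equal sums of FPKM (2.47 and -0.76). SNAI2 stood at 25.0 against 0.529 FPKM on day 3 and at 2.66 against 23.9 on day 7, SPARC at 32.4 against 329 FPKM on day 7, and the day 14 median was -0.36. CDH11 changed sides too, at 18.6 against 0.730 and then 6.61 against 41.5 FPKM. Not all members did. CDH2 was higher in the positive fraction on both days (63.9 against 6.28, then 66.4 against 43.0). FN1 was at 58.1 against 50.4 on day 3 and 60.2 against 408 on day 7.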

How the results depend on the processing

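Leaving out genes listed at 0, and leaving out the day 7 NKX2-5+ library, were alternatives chosen after the data were seen, and the others were planned. A pseudocount cannot change the direction of a ratio, and a smaller one cannot shrink it, so those outcomes were fixed in advance. All 328 named ratios of at least 4-fold, largely picked as the largest in these data, kept their direction under the alternative scalings. Of them, 328, 199, 287, 310 and 307 stayed at least 4-fold (pseudocount 0.1, pseudocount 5, equal sums, median-ratio scaling, and without small RNA and histone genes). Of 182 list medians (sort genes included), 52 were called, of which 52, 24, 44, 43 and 43 stayed called in that order, with 17, 0, 27, 3 and 5 others gained. Dropping the minimum FPKM moved no count by over 1.5 times. A larger pseudocount shrinks every ratio of low genes. Scaling to equal sums shifts every ratio of a pair by the ratio of its FPKM sums, apart from the pseudocount. Those sums were 414781 in day 7 NKX2-5- and 108220 in NKX2-5+, with MIR612 alone 51.6% of the NKX2-5- sum. The same scaling raises all values, since every sum was below 1000000, while the pseudocount of 1 and the minimum of 5 stayed fixed. Both rules are therefore looser at equal sums, and more low genes can be called. In the day 3 pair the sums were near equal (179685 and 175224), yet both counts grew. What else lies behind the shifts below was not tested.

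Counts are given as higher and lower. With a pseudocount of 0.1, day 14 aMHC+ over day 7 NKX2-5+ had 72 lower genes (main 44) and 11 called lists (main 7), and 2 lists lay on opposite sides in the sorted contrasts (main 1, the mesenchymal list), definitive endoderm being the other. With a pseudocount of 5 that number was 0, and at equal sums the 1 such list was BMP targets (-1.01 and 1.63) instead. With a pseudocount of 5 gene counts were 100 and 43 for the day 3 pair, 40 and 85 for the day 7 pair, 114 and 46 for CD13+/ROR2+ over hESC, 33 and 31 for CD13-/ROR2- over hESC, 103 and 190 for day 7 over day 3, and 162 and 15 for day 14 over day 7. Called lists in the same order numbered 2, 5, 4, 1, 9 and 2 (main 6, 9, 10, 4, 15 and 7), and in the day 3 pair cardiac mesoderm and pluripotency remained.

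At equal sums the counts were 487 and 512 (day 3 pair), 2081 and 129 (day 7 pair), 130 higher (day 14 pair), 792 and 328 (CD13+/ROR2+ over hESC), 437 and 112 (CD13-/ROR2- over hESC), 1049 and 787 (day 7 over day 3) and 592 lower (day 14 over day 7). Called lists were 14 in the day 7 pair, 3 in the day 14 pair (main 1), 8 for CD13-/ROR2- over hESC and 12 for day 14 over day 7. The immediate early median of the day 7 pair turned from -1.07 to 0.28. Median-ratio scaling gave 166 higher genes in the day 7 pair, 404 and 282 for day 7 over day 3, and 209 and 111 for day 14 over day 7. Without small RNA and histone genes, the rest rescaled to equal sums, the counts were 171 and 179 (day 7 pair), 14 and 0 (day 14 pair), 437 and 274 (day 7 over day 3) and 119 and 152 (day 14 over day 7). Without genes listed at 0 they were 16 and 1 for the day 14 pair, and 40 lower for CD13-/ROR2- over hESC. No paired analysis was possible because each group has 1 library.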

Other observations

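All tests in this part were chosen after the values were seen, and so were the genes named here outside the fixed rule. Both day 14 libraries held the somatostatin gene SST at 278 (aMHC+) and 394 FPKM (aMHC-), against at most 1.68 in the other 5 libraries. LMO2, a transcription cofactor gene of blood and endothelial precursors, stood at 26.4 and 64.7 FPKM on day 14 and at most 4.89 elsewhere, while GHRH stood at 15.6 and 7.62. The delta globin gene HBD was at 19.1 and 26.9 FPKM and listed at 0 in the other 5. Skeletal alpha-actin (ACTA1) was at 570 and 281 FPKM on day 14 and at most 5.49 before. The endothelial genes CDH5 (6.17 FPKM), ESAM (6.12), TEK (3.82) and PLVAP (15.6) were highest in day 7 NKX2-5-, but FLT1 (22.4) and KDR (16.2) in day 3 CD13-/ROR2-, EGFL7 (6.82) in day 14 aMHC- and VWF (1.14) in day 3 CD13+/ROR2+.

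GYPB (73.7 FPKM) and GYPE (30.3) were high in day 3 CD13+/ROR2+ and at most 0.464 in any other library; these close paralogs may share reads, which was not tested. CHCHD2 was at 0.171 FPKM in hESC, 23.3 and 26.1 in the day 3 CD13+/ROR2+ and CD13-/ROR2- libraries, 19.1 and 30.4 in day 7 NKX2-5+ and NKX2-5-, and 0.0836 and 0 on day 14. The metallothionein genes MT1G and MT1H were at 37.6 and 45.0 FPKM in hESC and at most 0.538 elsewhere. MIR612 (66826 and 213912 FPKM) and SNORD12B (10703 and 37270) were high in hESC and day 7 NKX2-5-, which carry the same index sequence per the labels, and were listed at 0 in the other 5 libraries. Sequencing lanes and runs are not known. With 1 library per group, an effect of lane or run could not be told apart from a difference between groups.

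Sarcomere transcripts in day 7 NKX2-5- could come from NKX2-5+ cells carried over in the sort. Carryover at one share would put that share of the NKX2-5+ level under every gene. The 5 lowest quotients (NKX2-5- over NKX2-5+) among 237 genes of at least 50 FPKM in NKX2-5+ were 1.65% (CKM), 1.68% (NKX2-5), 2.10% (NPPA), 2.18% (MYL3) and 3.73%, while the 22 sarcomere genes of at least 5 FPKM had a median quotient of 19.0%, and 19 of 22 exceeded 2 times the fifth lowest. These values argue against carryover of cells with the average NKX2-5+ profile as the whole cause. The genes with the lowest quotients include the sort gene NKX2-5 and MYL3, itself on the sarcomere list. Carried-over cells with lower levels of those genes than the average cannot be judged this way. A share of about 2% of average cells stays open. So does an untested biological reading, that some cells in this fraction express sarcomere genes with little NKX2-5.

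Plasma protein transcripts in day 7 NKX2-5+ (APOA2 38.7, AFP 14.9 FPKM) could likewise come from NKX2-5- cells. APOA2 already stood at 27.0 FPKM in day 3 CD13+/ROR2+, where AFP was at 0.0255, so its day 7 level may not need such a source. Carryover of the whole NKX2-5- fraction at one share is argued against, since S100A10, BGN, ANXA1, PDGFRB and DCN had quotients (NKX2-5+ over NKX2-5-) of 2.47% to 3.13%, and 12 of 12 hepatic list genes exceeded 2 times the highest of these, with a median of 17.8% and a range of 11.7% to 25.7%. The log2 quotients of these 12 genes had an SD of 0.388, and 3.48% of 10000 random gene sets from 4573 genes, not matched on level, had one as small. A small SD would follow from 1 hepatic-like source, whether free RNA or cells, behind both libraries. Genes regulated together could give it under other causes too, so it does not single out that source. Whether hepatic-like cells carry NKX2-5 stays open and was not tested.

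Of 15 definitive endoderm genes, 7 were higher and 2 lower in the library labelled mesoderm progenitor than in the one labelled endoderm progenitor. After median-ratio scaling these counts were 5 and 2. HHEX was at 7.43 against 0.577 FPKM, while FOXA2, at 3.88 against 0.0874, stayed under the minimum of 5 FPKM and is not among the 7. The library labelled endoderm progenitor had kept pluripotency transcripts, with 0 of 17 past the size rule against hESC. Against hESC, 2 of the 15 endoderm genes were higher in that library. In the library labelled mesoderm progenitor 8 were higher and 2 lower. A swap of the 2 day 3 libraries is argued against by the sort genes, since the smaller of the log2 ratios of ANPEP and ROR2 was 2.37 in favour of the library labelled CD13+/ROR2+. Endoderm cells inside the CD13+/ROR2+ gate could give these 7 higher genes, but so could mesoderm cells that express these genes, and a bulk library keeps this open, so that they cannot be told apart. GATA6 stands on both the endoderm and the mesoderm list.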
